A study of Arabidopsis thaliana with 4 samples.

How the data were processed

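Messenger RNA was selected with oligo(dT) from seedling RNA and sequenced on the Illumina platform, per the labels' protocols. The submitters' processing notes name Bowtie2 2.2.2 and the TAIR10 genome. How reads were assigned to genes, how reads matching several genes were treated and whether strand was used are not given in the sources used here. The authors deposited 1 table per library with RPKM (reads scaled by transcript length and library depth) for 27416 gene models, 1 per locus.

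The test planned for counts was replaced, because the deposited values are RPKM, by the test planned for normalized values. Values were taken as log2(RPKM + 1), and genes with at least 1 RPKM in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3 (linear model on the group, empirical Bayes moderation with an intensity trend, Benjamini-Hochberg adjustment over the 19201 genes tested). A log2 fold change on this scale understates the change of low genes. Ratios quoted as fold are ratios of the mean RPKM of the groups, and a call is an adjusted p under 0.05. Counts of genes changed at least 2-fold use the log2(RPKM + 1) scale. The libraries were counted as replicates because the labels give them as separate samples.

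The depth of each library was recovered from the values. Ratios of low values between libraries and exon lengths gave whole-number denominators, and at these depths all rows above 0 (100% of 24360) were whole reads within 0.001 reads. Of the tested rows, 15.9% were whole at the annotated length and the rest at a fitted length, which fixes their reads up to a whole-number factor. With the depth of 1 library set off by 0.1%, 6.8% of 500 rows checked were whole, against 100% at the recovered depths. The reads recovered on gene rows summed to 100.8% of the denominators. Fitted lengths that are too long and reads counted for more than 1 gene are both open, and neither was tested. The denominators are taken as the reads behind the RPKM values (28524534, 28098772, 27065174 and 24436863). Intervals and floors from reads (3 counts per library for a value of 0) cover counting error only.

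Genes were named from the TAIR10.1 reference annotation, which matched 26719 of the 27416 rows by locus code. Coordinates are those of TAIR10.1. GC content and length were available for 98.8% of the tested genes.

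Before the data were examined, 40 gene lists were fixed, 32 of pathways and 8 of organ or cell type markers, with 647 members written. Of these, 15 were left out because the annotation table gave no such name. Each list was tested with camera on the limma fit with a preset correlation of 0.01 and adjusted over the 40 lists, and 19 lists passed, 7 higher and 12 lower in CNT1. With an estimated correlation, which has 2 residual degrees of freedom to draw on, camera called 0 lists, the lowest adjusted p being 0.302 and 6 lists having an unadjusted p under 0.05. fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, called 33. Counts of members are over all genes tested. Adjusted over the list alone, they were equal in 36 lists, and the other 4 are given with their counts. The named genes were CRY1, the 10 called genes with the largest fold change in each direction among those with a mean of at least 5 RPKM and no overlap between the groups, and up to 3 called genes per direction and list by adjusted p. Not all of these are printed.

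The alternatives fixed before the data were examined were quantile and upper-quartile scaling, no low-value filter, a mean of at least 5 RPKM, limma without the trend, limma-voom on the recovered reads, a pseudocount of 0.1, the replicate number as a block, leaving out each library, leaving out organelle genes or the 20 most abundant genes, a correction for GC content and length, a 2-fold minimum, camera with an estimated correlation and fry. Median-of-ratios scaling and a search for chromosome clusters among calls of at least 2-fold were added after seeing the data. DESeq2 and edgeR were not run: the design fixed before the data were examined kept them for files that hold counts, and limma-voom is the only fit to recovered reads.

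The limma script was tested on simulated data for 19055 genes, with the recovered depths and mean reads of the real genes and an assumed dispersion of 0.002, in which 200 genes changed. It recovered 52% of the 50 genes changed 1.25-fold, 98% of the 50 changed 1.5-fold and 100% of those changed 2-fold and 4-fold, with 18 false calls. The dispersion was assumed, so these shares hold for that spread and that number of changed genes. Permutation tests were run with Python 3.11.15 and scipy 1.17.1, and tables were handled with pandas 2.3.3 and numpy 2.4.6.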

Results

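The series holds 4 RNA-seq libraries of poly(A) RNA from whole Arabidopsis thaliana seedlings of the Col-0 ecotype. All seedlings lacked functional cry1, the gene of the blue-light receptor cryptochrome 1, and carried 1 of 2 transgenes under the 35S promoter. In the group called CNT1 (2 libraries), the transgene encoded the N-terminal photolyase homology region of CRY1 with a nuclear localisation signal and yellow fluorescent protein. In the group called CNT1-G283E (2 libraries), it encoded the same fusion with the G283E substitution. Seeds were kept cold for 3 days, given white light for 12 h and then grown for 4 days in blue light of 15 μmol/m2/s. The comparison asked which genes are regulated by CNT1, and log2 fold changes are CNT1 minus CNT1-G283E throughout. The deposited RPKM values came from 28524534 and 28098772 reads in CNT1 replicates 1 and 2, and from 27065174 and 24436863 reads in CNT1-G283E replicates 1 and 2, as recovered from the values themselves. The labels give the replicates as separate samples but do not say that they came from separate cultures, so the p-values measure the spread between these samples, which may be technical. They do not say either whether each genotype is 1 transgenic line, so a difference between the groups is not separated from the insertion site or level of the transgenes.

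CRY1 (AT4G08920, chromosome 4, 5723651 to 5727268 in TAIR10.1) was read at 824 ± 1.56 RPKM in CNT1 and 1094 ± 82.0 RPKM in CNT1-G283E (mean ± SD, n = 2 each). The difference was -0.41 ± 0.058 (log2, SE), with a limma adjusted p of 0.000534. Both groups carry a CRY1 transgene, and a gene-level value separates neither transgene from endogenous transcript nor the 2 transgenes from each other, so CRY1 does not check the labels. The lower CRY1 value belongs to the CNT1 group.

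Gene expression differed widely between the groups. Of 19201 genes tested, 11530 passed an adjusted p of 0.05 in limma, 5964 higher and 5566 lower in CNT1. At least 2-fold changes on the log2(RPKM + 1) scale numbered 755 higher and 1009 lower. Among genes of at least 5 RPKM, the replicates differed by a median of 3.64% in CNT1 and 5.09% in CNT1-G283E, and libraries of different groups by 18.7% and 18.8%. The first principal component, with 94.4% of the variance, separated the groups. Recovered reads differed between replicates by more than sampling noise, with a chi-square per degree of freedom of 1.78 within CNT1 and 4.78 within CNT1-G283E. With limma-voom on the recovered reads, 1012 genes were at least 2-fold higher and 1564 lower, and with a pseudocount of 0.1 the counts were 1023 and 1453.

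**Figure D1:**
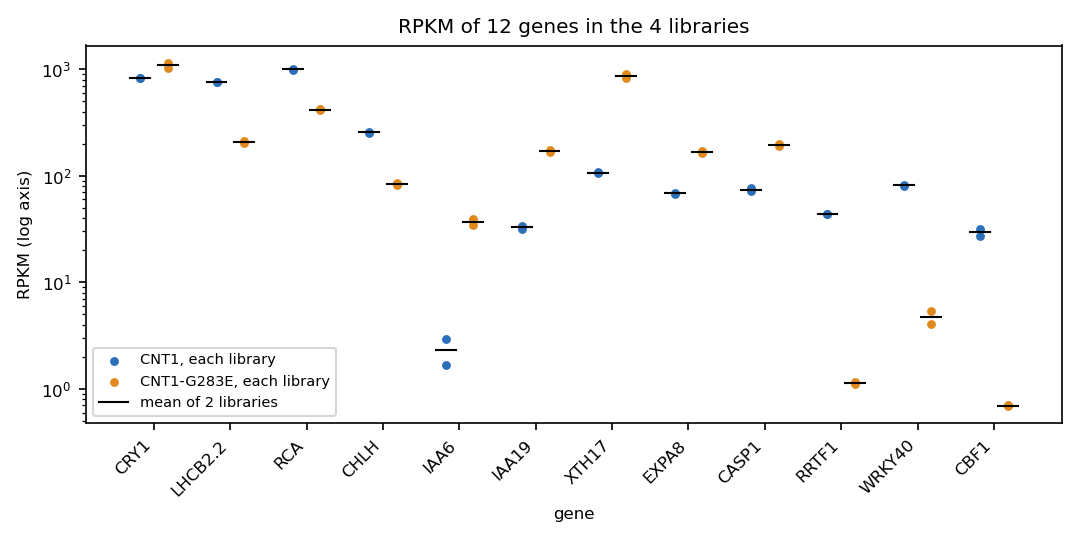
RPKM (log axis) of 12 genes in each library (points, 2 per group) with the mean of 2 libraries (black bar), CNT1 in blue and CNT1-G283E in orange. LHCB2.2, RCA, CHLH, RRTF1, WRKY40 and CBF1 were higher in CNT1, and CRY1, IAA6, IAA19, XTH17, EXPA8 and CASP1 lower, with no overlap between the groups.

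Genes of photosynthesis were higher in CNT1 almost without exception. All 17 light-harvesting antenna genes of the list rose, 15 of them at least 2-fold, with a median log2 fold change of 1.5. Of 9 tested genes with an LHCB symbol, 8 rose and 1, outside the list, fell. LHCB2.2, a chlorophyll a/b-binding protein of photosystem II, was read at 756 ± 1.45 RPKM in CNT1 and 210 ± 6.40 in CNT1-G283E (SD, n = 2), a ratio of 3.61. All 24 nuclear genes of the photosystems and electron transport rose, with a median of 1.08, among them PSBQA of the oxygen-evolving complex at 1.69 ± 0.042 (log2, SE) and the plastocyanin gene DRT112 at 1.52 ± 0.043. All 11 Calvin cycle genes rose, with a median of 1.2. RCA, encoding rubisco activase, went from 418 ± 2.19 RPKM in CNT1-G283E to 996 ± 2.56 in CNT1 (SD, n = 2), a ratio of 2.38. Of 19 chlorophyll synthesis genes, 18 rose, with a list median of 0.98. CHLH, a magnesium chelatase subunit, was 3.06-fold and CHLI1, another subunit, 2.94-fold higher. The exception was GLK2, a transcription factor of chloroplast development, at -0.12 ± 0.040 (adjusted p = 0.0364), a call lost under 7 alternatives. With camera and a preset correlation, the adjusted p was 1.09e-11 for the antenna, 3.23e-13 for the photosystems, 1.03e-07 for the Calvin cycle and 9.56e-10 for chlorophyll synthesis. With an estimated correlation the adjusted p was 0.302 for the first 3 lists and 0.393 for chlorophyll synthesis. Root markers were lower in the same libraries, with a median of -1.39. The LHCB1 and RBCS genes share near-identical copies, so the split of reads among them is uncertain.

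Auxin-responsive genes were lower in CNT1, in the same libraries in which root markers had a median of -1.39 and xylem and phloem markers of -0.90. Of 21 Aux/IAA and GH3 genes, which encode early auxin-response repressors and auxin-conjugating enzymes, 20 fell and 1 rose, with a median of -0.98. IAA19 was read at 33.0 ± 1.59 RPKM in CNT1 and 171 ± 6.06 in CNT1-G283E (SD, n = 2), a 5.19-fold lower level, and IAA3 was 3.49-fold lower. The gene that rose was IAA20, at 0.39 ± 0.065 (log2, SE). Of 26 SAUR genes, small auxin up RNAs linked to cell expansion, 24 fell, 18 of them at least 2-fold, and SAUR51 rose by 0.59 ± 0.156, a call lost without CNT1 replicate 2 and without CNT1-G283E replicate 1. SAUR19, SAUR21 and SAUR22, near-identical neighbours whose reads may be shared, were 2.37-fold, 2.38-fold and 2.19-fold lower. Of 15 genes of auxin synthesis and transport, 12 fell and 2 rose, and adjusted over the list alone 12 fell and 3 rose. YUC8, an auxin synthesis enzyme, was 4.69-fold lower at 6.03 ± 0.258 RPKM in CNT1 against 28.29 ± 2.63, while YUC9 was 2.40-fold higher. The camera adjusted p was 9.56e-10 for Aux/IAA and GH3, 1.35e-10 for SAUR and 0.0012 for synthesis and transport, and the adjusted p with an estimated correlation was 0.302 for each of the 3.

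Genes known as targets of the PIF transcription factors in shade followed the same direction, again with lower root (median -1.39) and xylem and phloem (median -0.90) markers. The agreement is partly that of shared genes. IAA19, IAA29, YUC8 and YUC9 are also in the auxin lists and BEE1 in the brassinosteroid list. XTH15 is also in the xyloglucan endotransglucosylase list and HFR1 among the light-signalling activators. Of 20 tested, 17 fell, 10 at least 2-fold, and 2 rose, with a median of -1.02. PRE1, a growth-promoting bHLH protein, was 9.64-fold lower, at 3.56 ± 0.531 RPKM against 34.4 ± 1.03 (SD, n = 2), and HAT2, a homeodomain-leucine zipper gene, was 2.52-fold lower. YUC9 and HAT3 rose, by 0.84 ± 0.129 and 0.14 ± 0.050 (log2, SE), and the HAT3 call was lost in the 3 other scalings, with limma-voom and in further alternatives. Of 19 brassinosteroid genes, 15 fell and 1 rose, with a median of -0.52. The synthesis enzymes DWF4 and BR6OX2 were 2.77-fold and 2.56-fold lower, IBH1, a growth-repressing bHLH protein, was 3.38-fold lower, and the synthesis enzyme CYP90D1 was 3.18-fold higher. The camera adjusted p was 1.90e-06 for the PIF targets and 3.09e-05 for brassinosteroid, and with an estimated correlation the adjusted p was 0.302 for both. Gibberellin genes moved both ways, 7 higher and 8 lower of 19, with a median of -0.13, a mean of 0.05 and a camera adjusted p of 0.58 with direction down, while fry gave direction up (0.0447). GA3OX1, which makes active gibberellin, rose from 12.5 ± 0.179 to 98.8 ± 0.103 RPKM (SD, n = 2) and GA3OX2 was 38.3-fold higher, while GA20OX1, acting a step earlier, was 6.98-fold lower.

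Cell wall genes were split, in the same libraries in which root (median -1.39) and xylem and phloem (median -0.90) markers were lower. Of 23 xyloglucan endotransglucosylase genes, which remodel wall xyloglucan, 15 fell and 6 rose, with a median of -0.53. XTH17 was read at 107 ± 1.88 RPKM in CNT1 and 867 ± 56.7 in CNT1-G283E (SD, n = 2), while XTH6 was 2.73-fold higher. Of 18 expansins, which loosen the wall, 11 fell and 3 rose, with EXPA5 4.66-fold and EXPA8 2.47-fold lower and EXLA3 3.44-fold higher. The camera adjusted p was 0.00896 for the first list and 0.0222 for the expansins, and the adjusted p with an estimated correlation was 0.393 for both. Among 8 genes of primary wall cellulose synthesis, 3 rose and 5 fell, none 2-fold (camera adjusted p = 0.365), and with either CNT1 library left out none rose and 3 or 4 fell. KOR1, an endoglucanase, was at -0.34 ± 0.039 and CESA1, a cellulose synthase, at 0.14 ± 0.037 (log2, SE), the CESA1 call being lost without the trend, after GC and length correction and with either CNT1 library left out.

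**Figure D2:**
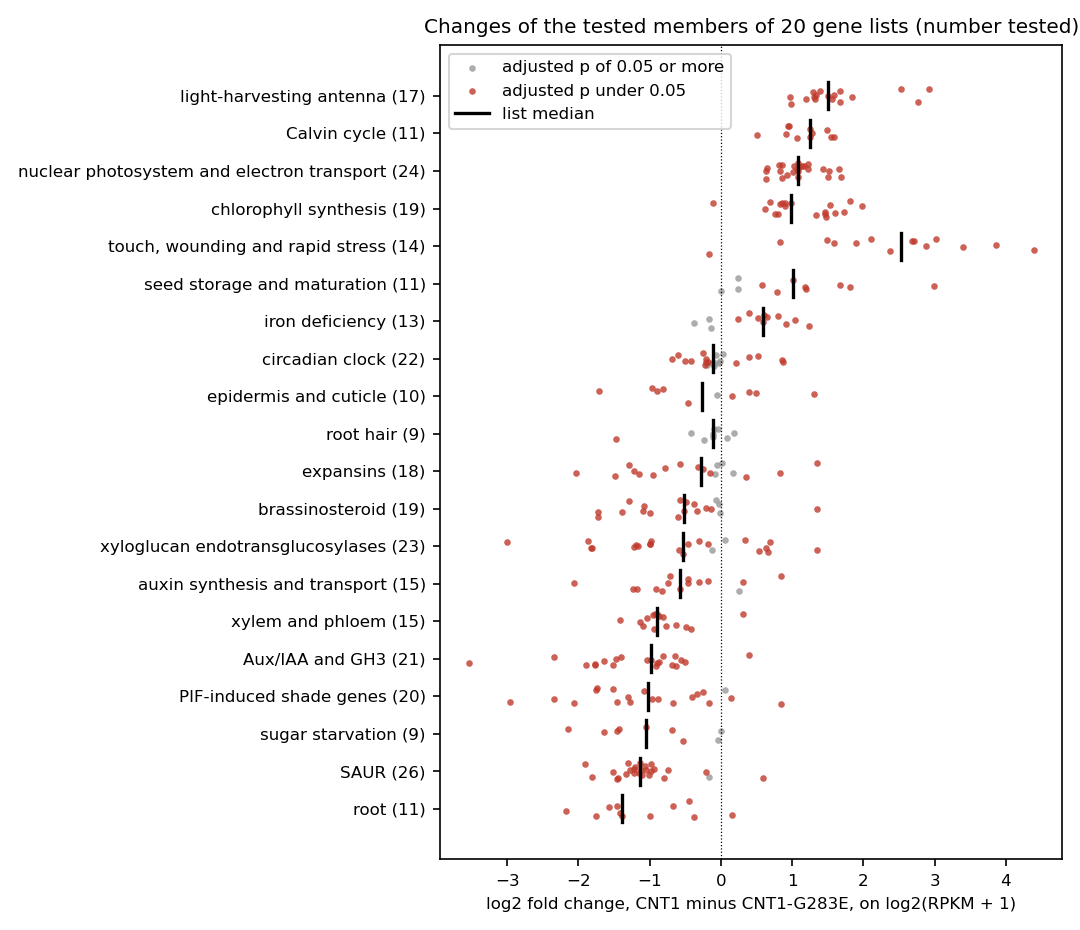
Log2 fold changes (CNT1 minus CNT1-G283E, on log2(RPKM + 1)) of the tested members of 20 gene lists, 1 point per gene, red where the adjusted p was under 0.05 and grey where it was not, with the list median as a black bar and the number tested in brackets. The 4 photosynthesis lists lie to the right, with medians from 0.98 to 1.5, and the SAUR and root lists to the left, with medians of -1.13 and -1.39.

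The regulators of light signalling showed smaller changes. Of 14 photoreceptor genes, 6 rose and 2 fell, none 2-fold (camera adjusted p = 0.704), with PHYD, a phytochrome, at 0.59 ± 0.091 and PHOT1, a blue-light receptor of phototropism, at -0.52 ± 0.043 (log2, SE). The median of that list was -0.01, its mean 0.09 and its camera direction up. Of 10 genes that promote seedling greening in light, 2 rose and 6 fell (camera adjusted p = 0.297). HFR1, a bHLH protein, was read at 52.8 ± 1.91 RPKM in CNT1 and 104 ± 4.03 in CNT1-G283E (SD, n = 2). Of 15 light-signalling repressors, 6 rose and 5 fell (camera adjusted p = 0.826, direction down, median 0.0007, mean -0.13), the 6 becoming 2 without CNT1 replicate 1 and 3 without CNT1 replicate 2, with PIF3 at 0.66 ± 0.050, PIF1 at -0.77 ± 0.083 and RUP1, a feedback inhibitor of the UV-B receptor, at -1.12 ± 0.092. Of 22 clock genes, 5 rose and 9 fell (camera adjusted p = 0.249), LHY at 0.86 ± 0.070 and PRR7 at -0.50 ± 0.057. Of 15 flavonoid and anthocyanin genes, 4 rose and 7 fell, 5 and 7 adjusted over the list alone (camera adjusted p = 0.421, median -0.16). Without CNT1-G283E replicate 1 the median was 0.17, and without CNT1-G283E replicate 2 it was 0.22, each over 11 genes. The low-value filter was applied again in these fits, so the genes behind these medians are not the same 15. MYB75, an activator of anthocyanin synthesis, was 6.28-fold lower, while CHS, the first enzyme of the pathway, was 1.36-fold higher. Among 8 genes of photoprotection and DNA repair, 4 rose and 2 fell, 1 falling without CNT1 replicate 1 or without CNT1-G283E replicate 1 (camera adjusted p = 0.353), with PSY, a carotenoid synthesis enzyme, 1.85-fold higher.

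The largest rises, ranked on log2(RPKM + 1) among genes with a mean of at least 5 RPKM and no overlap between the groups, began with AT5G03350, a legume lectin family gene (31.7-fold), and included several stress-responsive transcription factors. RRTF1 (chromosome 4, 16451876 to 16453260 in TAIR10.1), a redox-responsive AP2/ERF factor, was read at 43.9 ± 0.129 RPKM in CNT1 and 1.14 ± 0.0225 in CNT1-G283E (SD, n = 2; limma adjusted p = 2.73e-08). ORA47 was 34.5-fold, CBF1, a regulator of cold-response genes, 42.3-fold, ERF13 32.7-fold, WRKY40 17.2-fold and DDF1 77.8-fold higher. AT1G19210, a gene of the same AP2 class, had 789 reads in CNT1 and 2 in CNT1-G283E (reads recovered with a fitted length), a ratio of 359 corrected for depth with an exact 95% counting interval of 99.0 to 2968. Outside these factors, AT5G60800 of the heavy metal transport superfamily was 20.8-fold and AT4G29780, annotated as a nuclease, 18.8-fold higher. Of 14 genes induced within minutes by touch, wounding or other stress, 13 rose, 12 at least 2-fold, with a median of 2.53. ZAT12, a zinc finger factor of stress responses, was 6.87-fold higher, and the exception was TCH3, a calmodulin-like touch gene, at -0.17 ± 0.049 (log2, SE), a call lost without the trend or with either CNT1 library left out. The camera adjusted p was 1.03e-07, and 0.493 with an estimated correlation, which was 0.938 for this list.

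The lists of cold, drought and abscisic acid, jasmonate, ethylene, salicylate and immunity, and heat shock did not pass camera in the main fit. Of 18 cold, drought and abscisic acid genes, 11 rose and 7 fell (adjusted p = 0.165), RD29A at 372 ± 2.64 against 147 ± 8.15 RPKM and RD22 at 140 ± 0.0539 against 331 ± 18.5 (SD, n = 2). Of 18 jasmonate genes, 10 rose and 6 fell (adjusted p = 0.338), with the repressor JAZ1 3.52-fold higher and the storage protein gene VSP2 5.26-fold lower. Of 14 ethylene genes, 9 rose and 3 fell, 1 falling without CNT1 replicate 1 (adjusted p = 0.102), with the synthesis enzyme ACS6 6.24-fold higher and ACO4 2.13-fold lower. Of 10 salicylate and immunity genes, 5 rose and 1 fell, 6 and 2 adjusted over the list alone (adjusted p = 0.224, and 0.0282 without a low-value filter), and with either CNT1 library left out 2 of 7 rose, with WRKY33 6.12-fold higher. Heat-shock genes gave 4 higher and 4 lower of 10, 2 of 8 being lower without CNT1-G283E replicate 1 (adjusted p = 0.894, direction up, median -0.05, mean 0.10), and the factor HSFA2 was 14.0-fold higher.

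The largest falls, ranked in the same way, spread over several classes. AT4G37220 (chromosome 4, 17515042 to 17516162 in TAIR10.1), a cold acclimation WCOR413 family gene, was read at 10.3 ± 0.675 RPKM in CNT1 and 162 ± 0.323 in CNT1-G283E (SD, n = 2; limma adjusted p = 2.64e-08). IAA6, another Aux/IAA gene, was 16.0-fold, UGT84A3, a glycosyltransferase, 29.1-fold, and the glycine-rich protein gene AT1G04660 17.1-fold lower. PRP2, a proline-rich wall protein, fell from 587 ± 26.5 to 63.4 ± 0.438 RPKM. GH9B15, a glycosyl hydrolase, was 16.1-fold, AT5G03090 11.1-fold, AT4G11190, dirigent-like, 9.97-fold and AT4G17470, of the hydrolase superfamily, 9.90-fold lower. UGT84A3 had the largest standard error of these (0.215, log2), with 26.4 ± 10.1 RPKM in CNT1-G283E.

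Genes induced by sugar starvation were lower, 7 of 9 falling and none rising, with a median of -1.05 (camera adjusted p = 0.000118, and adjusted p = 0.393 with an estimated correlation). DIN10 was 2.78-fold and BCAT2, of branched-chain amino acid breakdown, 3.16-fold lower. Iron-deficiency genes were higher, 10 of 13 with none falling (1 without CNT1-G283E replicate 2) and a median of 0.59 (camera adjusted p = 0.0129, and adjusted p = 0.493 with an estimated correlation), with the transporter OPT3 2.40-fold higher. Phosphate-starvation genes were mostly lower, 9 of 13 with 2 rising (camera adjusted p = 0.0324, and adjusted p = 0.393 with an estimated correlation), PPCK1 at -0.96 ± 0.070 (log2, SE). That list did not pass after GC and length correction (0.0672), under the stricter filter (0.228) or without CNT1-G283E replicate 1 (0.0824). Nitrate genes gave 7 higher and 2 lower of 10, the 2 becoming 3 without CNT1-G283E replicate 1 and 1 without any other library (adjusted p = 0.0696), the nitrate reductase NIA2 2.3-fold higher and the transporter NRT1.1 1.76-fold lower, and passed after GC and length correction (0.0212), with limma-voom (0.0484), without CNT1 replicate 1 (0.0441), without CNT1 replicate 2 (0.0450) and without CNT1-G283E replicate 2 (0.0410). For the nitrate list, camera with an estimated correlation gave an adjusted p of 0.707. Glucosinolate genes gave 6 higher and 4 lower of 12, 7 and 4 adjusted over the list alone (adjusted p = 0.353). Of 23 cell cycle genes, 4 rose and 10 fell, 1 rising with either CNT1 library left out (adjusted p = 0.107), the mitotic cyclin CYCB1;4 being 2.63-fold lower. Of 6 genes commonly used as stable references, 5 fell and 1 rose, in all 3 other scalings too, and 4 fell and none rose with either CNT1 library left out, ACT2 at -0.59 ± 0.043 and ACT7 at -0.54 ± 0.039 (log2, SE). That list had a camera adjusted p of 0.0307, of 0.393 with an estimated correlation, of 0.0566 without the trend and of 0.0530 without CNT1 replicate 1.

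Markers of organs and cell types also moved. Of 11 root genes, 10 fell and 1 rose, with a median of -1.39 (camera adjusted p = 2.25e-05, and adjusted p = 0.302 with an estimated correlation). CASP1, a protein of the root endodermis, was read at 74.0 ± 3.88 RPKM in CNT1 and 195 ± 7.53 in CNT1-G283E (SD, n = 2), and the aquaporin TIP2;3 was 3.42-fold lower. SCR, of the root and shoot endodermis, was at 0.15 ± 0.056 (log2, SE), a call lost in 10 alternatives, the 3 other scalings among them. Of 9 root hair genes, LRX2, an extensin-like wall protein, fell 3.07-fold, and 8 did not pass the test (camera adjusted p = 0.385). Only 2 of the 9 have a mean of at least 5 RPKM, and the list median turned with the library left out. It was -0.33 without CNT1-G283E replicate 1 and 0.18 without CNT1-G283E replicate 2, with the low-value filter applied again. Of 15 xylem and phloem genes, 14 fell and 1 rose, with a median of -0.90 (camera adjusted p = 5.60e-06, and adjusted p = 0.393 with an estimated correlation), XCP2, a xylem peptidase, being 1.77-fold lower. Of 11 seed storage and maturation genes, 8 rose and none fell, 5 of 8 rising with either CNT1 library left out (camera adjusted p = 0.00266, adjusted p = 0.571 with an estimated correlation, and 0.133 under the stricter filter, which left 4 genes). The storage protein gene CRA1 was read at 27.6 ± 0.188 RPKM against 7.17 ± 1.06 (SD, n = 2). Epidermis and cuticle genes gave 4 higher and 5 lower of 10 (adjusted p = 0.288), with the lipid transfer protein LTP1 2.45-fold higher and the wax enzyme CER1 3.39-fold lower. Guard cell and stomatal lineage genes gave 5 higher and 3 lower of 11, 3 of 10 being higher without CNT1 replicate 2 (adjusted p = 0.931, direction up, median -0.13, mean 0.08), shoot meristem and leaf primordium genes 1 higher and 3 lower of 4 (adjusted p = 0.344) and trichome genes 1 higher of 2, and none without CNT1 replicate 2 (adjusted p = 0.826).

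The share of reads from plastid-encoded genes was 1.53% and 1.69% in the CNT1 libraries and 1.19% and 1.02% in the CNT1-G283E libraries. Mitochondrial genes took 0.0292% and 0.0310% against 0.0315% and 0.0243%. An exact permutation test of 2 against 2 libraries cannot go below a two-sided p of 0.333, so no p is given for these shares. Of 88 plastid genes tested, 71 were higher in CNT1 and none lower in limma. Poly(A) selection removes most organelle transcripts, and the values describe what remained.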

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

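Median-of-ratios scaling was chosen after seeing the data, and the other alternatives before. Between 8910 and 11866 genes were called under the alternatives that change the fit, against 11530, and scalings moved the median of all genes by less than 0.1. The replicate numbers did not pair the samples (correlation of same-number deviations -0.0231), and the replicate block called 11214 genes and 19 lists. Leaving out a library gave 8910 to 10838 calls, with the lone library assumed to vary like the other group. A 2-fold minimum left 1764 genes (755 higher, 1009 lower), and limma-voom gave 1564 genes at least 2-fold lower. CRY1 was lower under all alternatives (-0.48 to -0.33). Of 198 other genes named by the rule, 0 reversed in limma or limma-voom and 21 lost the call in some alternative, all 21 when a library was left out. The organelle share differed by 0.506 percentage points, and by 0.00221 for mitochondrial genes alone. DESeq2 and edgeR were not run: the design kept them for files that hold counts, and limma-voom is the only fit to recovered reads.

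With an estimated correlation camera called 0 lists in place of 19. For SAUR the unadjusted camera p went from 1.01e-11 to 0.0168, though its estimated correlation, -0.0217, was below the preset 0.01. The estimate was also below 0.01 for Aux/IAA and GH3, PIF targets, auxin synthesis and transport, root and reference genes. For these lists a higher correlation among members does not account for the lost call. It was above 0.01 for the other called lists, from 0.0285 for expansins to 0.938 for rapid stress. For those lists the part of the correlation in the lost call is not separated from the 2 residual degrees of freedom. The adjusted p rose to 0.302 for PIF targets, Aux/IAA and GH3, SAUR, auxin synthesis and transport, brassinosteroid, light-harvesting antenna, photosystem, Calvin cycle and root genes, to 0.393 for expansins, xyloglucan endotransglucosylases, chlorophyll synthesis, sugar starvation, phosphate starvation, reference genes and xylem and phloem, to 0.493 for rapid stress and iron deficiency, and to 0.571 for seed storage. The estimate, and the test that uses it, rest on 2 residual degrees of freedom. The fry test, which does not compare a list with other genes, called 33 lists. Those not called by camera were photoreceptors 0.0392, flavonoid 0.0319, photoprotection 0.0245, cellulose synthesis 0.0488, ethylene 0.00371, jasmonate 0.00161, salicylate 0.0356, cold and drought 0.00741, nitrate 0.0216, glucosinolate 0.0412, cell cycle 0.00365, meristem 0.0282 and epidermis 0.00618, and gibberellin in the opposite direction, 0.0447.

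Other list calls that changed were phosphate starvation (0.0672 after GC and length correction, 0.228 under the stricter filter, 0.0824 without CNT1-G283E replicate 1), seed storage (0.133 under the stricter filter, with 4 genes left), reference genes (0.0566 without the trend, 0.0530 without CNT1 replicate 1), salicylate (0.0282 with no low-value filter) and nitrate (0.0212 after GC and length correction, 0.0484 with limma-voom). The cause was not tested. Lists that did not pass reversed under the stricter filter for photoreceptors 0.895, light-signalling repressors 0.907, flavonoid 0.717, gibberellin 0.681 and guard cell 0.836, with limma-voom for guard cell 0.996, with no filter for heat shock 0.451 and trichome 0.846, and for heat shock without organelle genes 0.888 or without the 20 most abundant genes 0.863. With each library left out in turn, the adjusted p ran from 0.634 to 0.985 for photoreceptors, 0.382 to 0.985 for flavonoid, 0.411 to 0.985 for heat shock, 0.0415 to 0.0824 for phosphate starvation, 0.0410 to 0.129 for nitrate, 0.0123 to 0.0530 for reference genes, 0.648 to 0.992 for trichome and 0.816 to 0.992 for guard cell. Of these, directions turned without CNT1-G283E replicate 2 for photoreceptors, heat shock and trichome. They also turned without CNT1-G283E replicate 1 for flavonoid, where the repeated filter left fewer genes, and without CNT1 replicate 1 for guard cell.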

Other observations

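Gene families defined by the letters of their symbols were a search beyond the fixed lists, but members of those lists were not removed. IRX9 is in the xylem and phloem list, CYCB1;1, CYCB1;2 and CYCB1;4 in the cell cycle list. ERF5, ERF6 and ERF11 are in the rapid stress list. Families and lists can therefore share genes and are not independent. With camera and a preset correlation, 41 of 194 families passed an adjusted p of 0.05. None passed with an estimated correlation, a test on 2 residual degrees of freedom (lowest adjusted p = 0.759). Fasciclin-like arabinogalactan genes (FLA), which encode cell surface proteoglycans, were lower in CNT1, 13 of 14, with a median log2 change of -1.15. Arabinogalactan protein genes (AGP) gave 19 lower and 5 higher of 28, IRX genes of secondary wall synthesis 9 lower of 10, NAC transcription factors 33 lower and 5 higher of 50, and CYCB mitotic cyclins 8 lower of 9, in libraries in which xylem and phloem markers (14 of 15, median -0.90) and root markers (10 of 11, median -1.39) were lower too. Higher in CNT1 were PTAC genes of plastid transcription, 13 of 14 with a median of 0.89, RPS ribosomal protein genes, 19 of 24, CRR genes, 8 of 10, and ERF factors, 13 higher and 1 lower of 20. EMB genes, named for embryo-lethal mutants, gave 89 higher and 9 lower of 155.

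Of genes with at least 30 reads in each library of 1 group and 0 reads in both libraries of the other, 12 were read in CNT1 and 1, AT5G46940, in CNT1-G283E. These were picked after their values were seen, and for some of them the reads rest on a fitted length. PUM7, an RNA-binding pumilio gene, had 206 and 216 reads in the CNT1 libraries and 0 in both CNT1-G283E libraries (annotated length), at least 63.8-fold higher with a floor of 3 counts per library. KCS18, a fatty acid elongase of seeds, had 104 and 115 reads, at least 33.1-fold higher.

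Called genes did not cluster along the chromosomes more than chance when all calls were used (20 of 20 in the densest window of 20 tested genes, permutation p = 0.246, 100000 resamples), a test that saturates at this number of calls. With calls of at least 2-fold, a version added after seeing the data, the densest window of lower genes held 9 of 20 (permutation p = 0.00219). It lies on chromosome 1 from 10268421 to 10324826 in TAIR10.1 and contains SAUR62, SAUR63, SAUR64, SAUR66, SAUR67 and SAUR68, neighbouring members of 1 gene family. How reads matching several genes were treated is not given, so sharing of reads among them is not excluded, their calls are not independent and the p is too small to that extent. The densest window of higher genes held 7 of 20 (permutation p = 0.037), on chromosome 1 from 27377759 to 27445997. Among its called genes are the neighbouring loci AT1G72900, AT1G72910, AT1G72920, TIR, AT1G72940 and AT1G72950. Sharing of reads is not excluded there either, and the calls of neighbours may not be independent.

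Of the tests below, that of the genes flanking PUM7 was fixed before its result was seen. The GC and length correction and the fit without the most abundant genes were alternatives fixed before the data were examined. The other tests below were not fixed before their results were seen.

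Photosynthesis and chlorophyll genes were higher in CNT1 (70 of 71), and root markers lower. A smaller share of root tissue alone would raise shoot genes alike. The 71 genes lay 1.503 log2 units above the epidermis and cuticle genes (permutation p = 2e-05, the smallest 100000 resamples give, across genes, which are not independent replicates). Those 10 genes moved both ways (4 higher, 5 lower, SD 0.883), so they do not serve as a measure of shoot share. The 2 lists did not rise alike, but a smaller share of root as a part of the rise stays open. For the root markers a smaller share of root stays open: root genes lay -0.85 from root hair genes in mean log2 change (exact permutation p = 0.00692, across genes), but only 2 of the 9 root hair genes reach a mean of 5 RPKM. After GC and length correction 70 of the 71 remained higher, and without the 20 most abundant genes 65 of 66. The substitution in the transgene, the level and insertion site of the 2 transgenes and a change in the balance of cotyledon and hypocotyl stay open, and none of them was tested.

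Rapid stress genes were higher in CNT1 (13 of 14), which may have a technical source. After GC and length correction 13 of 14 were higher, and without the 20 most abundant genes 13 of 14. The list median was 2.53 in the main fit, 2.50 after the correction and 2.55 without those genes. Shifts this small could hardly undo such rises, so the counts by themselves decide little. The medians argue against GC content, length or those 20 genes as the source of most of the rise. Other technical sources stay open. Handling at harvest cannot be told apart from genotype: the CNT1 libraries differed by a median of 0.0486 log2 units in this list and the CNT1-G283E libraries by 0.270, so the list varied within a group, and the labels do not say which libraries were harvested together. A different time of harvest stays open too: morning and evening clock genes differed by 0.18 (exact permutation p = 0.511), but the labels give neither a harvest time nor a light-dark cycle. The morning mean averages opposite calls, LHY (0.86) and CCA1 (0.40) higher and PRR9 (-0.69) and RVE1 (-0.42) lower, with RVE8 not called. Of the evening genes only BOA (-0.23) and TOC1 (-0.21) were called, so a small difference of means does not show an unchanged clock. A biological origin in the transgene was not tested apart from these.

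PUM7, read in both CNT1 libraries and neither CNT1-G283E library, could reflect activation by a transgene inserted nearby. Of 10 tested flanking genes, 5 loci on each side, 0 were at least 2-fold higher in CNT1 in limma, which argues against strong activation that spreads to neighbours. Of the 10, 4 were called higher by less than 2-fold (AT1G78140 0.33, AT1G78170 0.30, AT1G78180 0.36 and AT1G78200 0.39, log2) and 2 lower, where 5964 of all 19201 tested genes were called higher. Activation of PUM7 alone, or with a weak effect on neighbours, stays open. All libraries came from seedlings with a transgene, so loss of PUM7 transcript in CNT1-G283E stays open as well and was not tested.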
